A study of Mus musculus with 54 samples.

How the data were processed

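Bone marrow progenitors of mice were profiled with MARS-seq, a plate-based single-cell RNA-seq method in which each sorted cell is lysed in its own well, the 3' ends of its mRNA receive a well barcode and a unique molecular identifier (UMI), and wells are amplified together as a pool. Each of the 54 GEO samples is 1 amplification pool of 192 wells, of which 190 received a single cell and 2 received none. All cells came from the progenitor fraction that lacks lineage markers and Sca1 and carries cKit. The labels give 8 groups: unsorted myeloid progenitors, 3 gates sorted inside the common myeloid progenitor (CMP) fraction, a conditional knockout of Cebpa with its control, and a knockout of Cebpe with its control.

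The count table deposited by the authors holds UMI counts for 27297 gene rows in 10368 wells, and it was used as raw counts. The well table deposited by the authors names the amplification pool, plate, sequencing batch, mouse identifier and description of each well, and for index-sorted cells the fluorescence intensity of surface CD34 and FcgR. Per the submitters' processing notes, bcl2fastq 2.15.0.4 and the genome build mm9 were used; the aligner and the steps from reads to UMI counts are not given in the sources used here. Of the gene rows, 11135 held no UMI and 2109 joined several symbols, so a value of a joined row cannot be given to 1 of its genes and is reported as uncertain. The values of Kit, B2m and Itga2b, all joined rows, are uncertain in this way wherever they are printed. The same holds for genes with near-identical copies, such as globins, Chi3l3 and Ly6c2, whose reads could have been split between copies. Coordinates are not printed, since the annotation at hand is of another build.

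The 54 pools held 27845961 UMIs in all, between 140748 and 854479 per pool. Single-cell wells with at least 500 UMIs were kept, which left 8399 of 10260 cells (81.9%) with a median of 2646 UMIs. Wells were sorted to hold single cells, so no doublet caller was run. The wells without a cell carried a mean of 12.5 to 212 UMIs per pool, and 0 of the 108 reached 500. No ERCC spike-in rows were found. All 1431 pairs of pools were compared over 2379 abundant genes. The lowest chi-square per degree of freedom was 1.40, so no pool was counted as a copy of another.

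For 36 pools the GEO label and the description in the authors' table named the same group, and for 18 pools they did not. The planned grouping by label was therefore changed after the tables were compared: results rest on the 36 pools where both sources name the same group. No Cebpe pool is among these, so the Cebpe comparison follows the authors' table. Grouping all pools by the GEO label, and grouping all of them by the authors' table, were added as alternatives after the data were seen. The authors' table gives 8 mouse identifiers for 8 descriptions, 1 per group. Each comparison is thus 1 animal identifier against 1, and the difference between animals has no replicate check. Whether an identifier names 1 mouse or several pooled mice is not given in the sources used here. As planned for that case, UMIs were summed per group and are given as values: CPM after TMM scaling of the summed counts, the log2 ratio, and its 95% interval (exact Poisson for a sum, exact binomial conditional on the total for a ratio, both covering counting error only). A count of 0 was set to a floor of 3 counts over the group, and the ratio is then a bound at that floor, not a 95% limit. Genes were counted as different in size at 2-fold or more with at least 100 CPM in the higher group.

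The amplification pool was used as the unit in a second set of tests. UMIs were summed per pool and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. These p-values measure the spread between amplification pools of 1 animal identifier per group, which may be technical. The unsorted progenitors and the sorted gates, 4 groups of wild-type background, were fitted together, so they share 1 estimate of the spread. Pools entered a test within a cell class with at least 20 cells of that class. Pool ranges given beside a group value are of TMM-scaled CPM, and standard errors of log2 ratios are over pools. The CPM of the targeted genes in each pool, with their figure, and those of flagged patterns, plates and single pools are without TMM scaling. On simulated data made from the real means, with 200 genes changed, the Cebpa test recovered 78% of 2-fold and 99% of 4-fold changes among 5161 genes. The Cebpe test recovered 60% and 92% among 7109 genes, and the Cebpe test within neutrophil- and monocyte-like cells 29% and 86% among 5398. The Cebpa test within erythroid-like cells recovered 73% and 97% among 3920 genes. Against unsorted cells the CD41 test recovered 40% and 87% among 8052 genes, the Flt3 test 56% and 91% among 8068, and the Irf8-GFP test 77% and 100% among 8073. Of the calls, between 4.17% (Cebpe within neutrophil- and monocyte-like cells) and 7.81% (Irf8-GFP) were false. Simulated pools were drawn independently, without the pairing of pools by plate, so recovery in the real pools may be lower.

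Cell classes came from the 2732 unsorted cells. They were log-normalised and clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, scaled within plates, 30 principal components, 15 neighbours, resolution 1.0), which gave 11 clusters. Component scores were rounded, since unrounded ones, and with them the clusters, changed with the number of processor threads. A cluster was named from at least 3 fixed markers among its 50 leading genes and otherwise stayed unnamed. Cells of every group were assigned to the cluster with the highest multinomial likelihood over 1185 genes. Of the unsorted cells, 86.7% returned to their own cluster, and 88.3% to their own class when their plate was held out of the profiles. A class therefore means the nearest unsorted cluster, not a type established apart from it. Differences in shares were tested by exact two-sided permutation of pools with Benjamini-Hochberg adjustment over 9 classes, in scipy 1.17.1. Pools came in pairs from 1 plate, and neither these tests nor those on genes model the plate. All splits of the pools were enumerated, also for the unsorted group, where resampling had been planned. Shares of pooled cells carry exact binomial 95% intervals; for a share of 0 the limit given is 3 counts of the total.

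Chosen before the data were examined were the tests, the cell type markers, 19 gene lists, the rule for named genes and most alternatives. The lists were primary and secondary granule proteins, heme synthesis, globins and erythroid membrane, MHC class II presentation, platelet proteins, lineage transcription factors, interferon-stimulated genes, S phase and mitosis, immediate early and heat shock genes, basophil and mast cell proteases, and markers of monocytes, neutrophils, erythroid, stem or multipotent, lymphoid or NK, eosinophil, dendritic and other bone marrow cells. The list called secondary granule also held tertiary granule proteins and the genes S100a8 and S100a9. Several lists share members, and the marker lists also served to name clusters. The named genes were 12 genes of the gates and knockouts, the 10 largest differences in each direction with at least 100 CPM, and up to 4 members per list; only part of these are printed. The alternatives were minimums of 1000 and 250 UMIs per cell, DESeq2 1.42.0 with its size factors, no filter on low counts, thinning each cell to 500 UMIs, classes assigned without 79 marker rows, clustering at resolutions of 0.5 and 1.5, leaving out each pool, leaving out controls whose strain label names Mx1-Cre, and the pool as the unit. GC content and length were taken from GENCODE M21 transcripts by symbol.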

Results

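Single-cell transcriptomes of mouse bone marrow myeloid progenitors were collected in 54 amplification pools by MARS-seq. Per the labels and the authors' table together, 16 pools held unsorted myeloid progenitors (2732 cells with at least 500 UMIs, median 3101 UMIs) and 3 sets of pools held sorted gates of common myeloid progenitors (CMP). The gates were CD41-positive (2 pools, 336 cells, median 1843.5 UMIs), Flt3- and Csf1r-positive (2 pools, 380 cells, median 2908) and Irf8-GFP- and MHC class II-positive (4 pools, 743 cells, median 2682). The Cebpa knockout had 8 pools (847 cells, median 1887) and its control 4 pools (558 cells, median 2895). Both carry the poly(I:C) treatment label, with no dose or time. Cebpe pools were grouped by the authors' table: 4 knockout pools (559 cells, median 3238) and 2 control pools (250 cells, median 3696). Each group came from 1 mouse identifier, so differences between groups are given as values with intervals covering counting error only. The tests quoted beside them take the amplification pool as the unit, and their p-values measure only spread between pools, which may be technical.

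The targeted genes were read in each pool before any comparison. In the Cebpa knockout, Cebpa had 1 UMI in each of 3 pools and 0 in the other 5. In Cebpa control replicates 3 to 6 it had 51, 64, 45 and 35 UMIs, or 73.8, 87.8, 152 and 115 CPM (in this paragraph without TMM scaling). Among the 18 pools whose label and table entry differ, the libraries labelled Cebpa control replicates 1 and 2 and Cebpe control replicates 1 and 2 had 0 Cebpe UMIs each, while Cebpa stood at 329, 338, 257 and 275 CPM. The authors' table calls these 4 pools Cebpe knockout. The libraries labelled Cebpa knockout replicates 3 and 4, which the table calls Cebpe control, had 34 and 23 Cebpa UMIs and 40 and 21 Cebpe UMIs. The libraries labelled Cebpe knockout replicates 1 and 2 had 1 and 0 Cebpa UMIs. In the libraries labelled Cebpe knockout replicates 3 and 4, Cebpa had 44 UMIs each. The labels do not say which part of either gene was deleted, and a 3' tag outside the deleted part would check nothing.

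**Figure D1:**
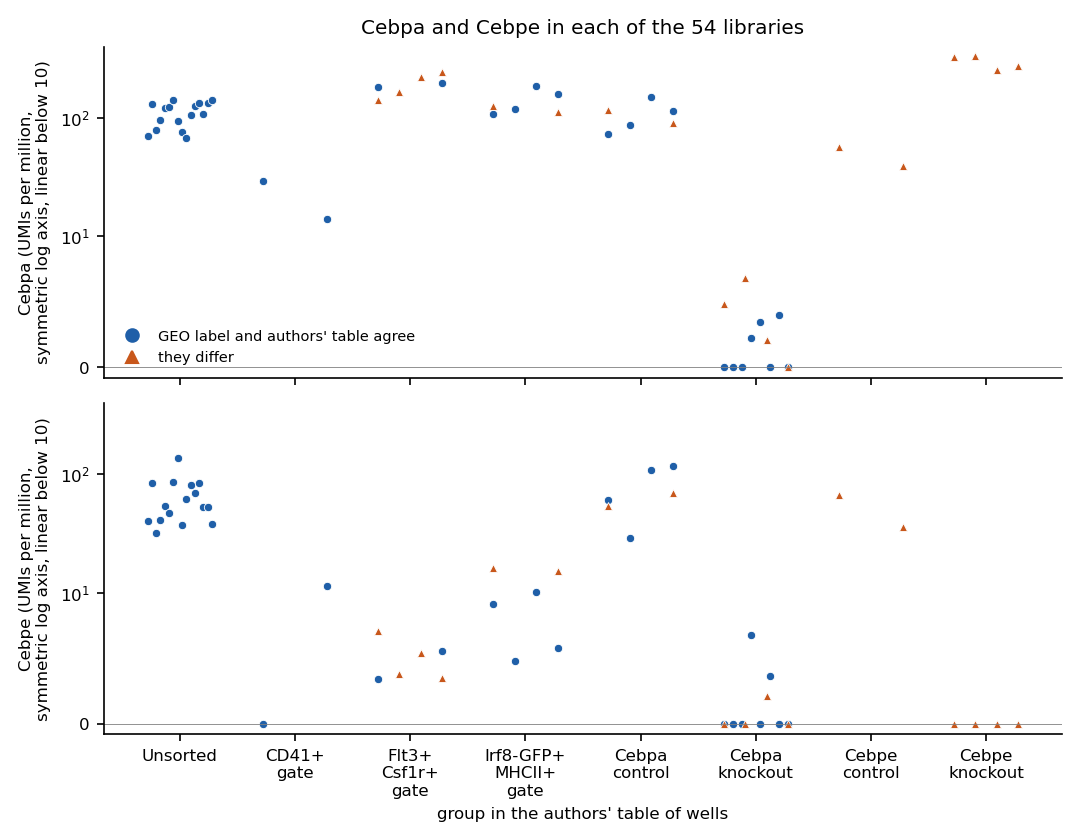
Cebpa and Cebpe CPM in each of the 54 amplification pools, grouped by the authors' table. Blue circles mark pools whose label and table entry name the same group; orange triangles mark pools where they differ.

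Unsorted progenitors formed 11 clusters, of which 9 took a name from fixed markers. Cells of the 2 erythroid-like clusters made up 27.7% of all (mean over 16 pools 27.7 ± 7.40 SD, range 13.0 to 36.7). Monocyte-like cells were 17.0%, neutrophil-like 14.2%, stem- or multipotent-like 11.5%, megakaryocyte-like 4.94%, basophil- or mast-like 4.21%, lymphoid- or NK-like 1.17% and dendritic-like 1.10%. The stem- or multipotent-like cluster was led by Flt3, Dntt and Satb1, with the markers Cd34 and Sox4 among its 50 leading genes. The 2 unnamed clusters held 18.3% of assigned cells. The larger of them (539 cells before assignment) was led by Apoe, Ptpn14 and Slc22a3, with F2r and Gata2 also among its leading genes. Gata2 encodes a transcription factor of stem, mast and early erythroid cells. The sort gates and the plate mix set these shares, and a class is the nearest cluster in expression.

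Surface intensity of CD34 and FcgR from the index sort differed between these classes, with pool ranges that overlapped for some, and neither was used for clustering. FcgR was high in monocyte-like and neutrophil-like cells (mean of pool medians 1753 ± 507 SD and 1503 ± 499.7, n = 16) with CD34 at 325 ± 79.8 and 233 ± 52.7. Basophil- or mast-like cells stood beside them, with FcgR at 1521 ± 712 and CD34 at 410.03 ± 199.7. Erythroid-like cells had the lowest FcgR (10.7 ± 3.92) and low CD34 (43.6 ± 10.6), and 239 of 756 such cells had FcgR values at or below 0. Stem- or multipotent-like and megakaryocyte-like cells lay between, with FcgR at 353 ± 144 and 260.4 ± 80.4 and CD34 at 255 ± 60.5 and 179.5 ± 65.1. Unnamed cells were lower in both, with CD34 at 63.4 ± 22.1 and FcgR at 103.5 ± 30.7. Dendritic-like cells had CD34 at 149.8 ± 64.9 and FcgR at 212 ± 136, and lymphoid- or NK-like cells had CD34 at 30.3 ± 19.9 and FcgR at 559.8 ± 424. Replicates 3, 4, 15 and 16, from 2 of the 8 plates, stood apart: their monocyte-like cells had FcgR of 871 to 1179 and CD34 of 431 to 491, against 1611 to 2366 and 259.5 to 309.5 in the other 12 pools. The intensities came from 2716 cells of 1 mouse identifier, and no test was run on them.

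**Figure D2:**
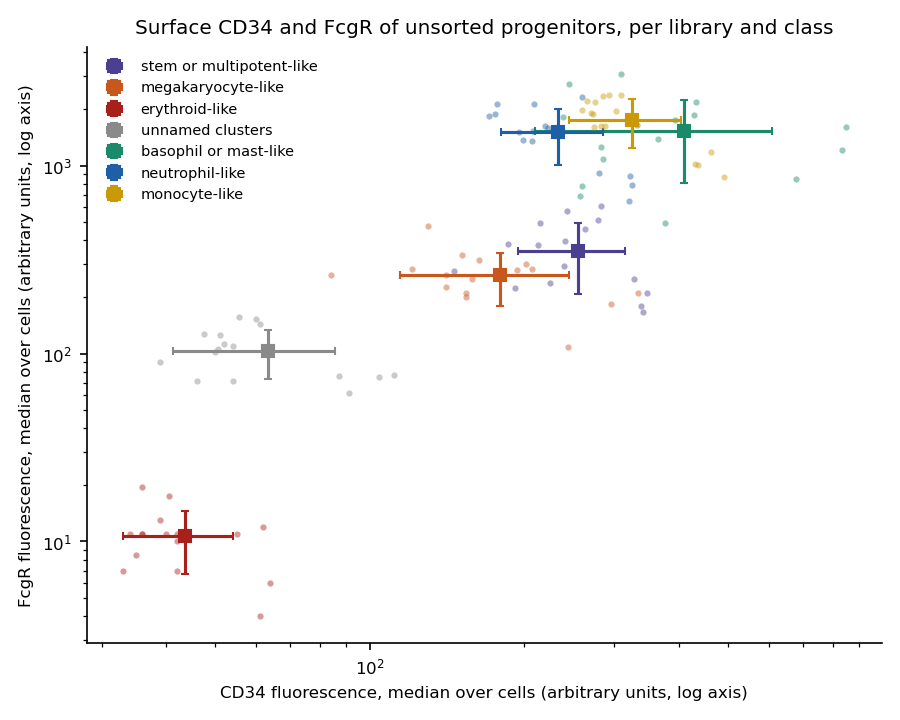
Surface CD34 against FcgR intensity of unsorted progenitors by cell class. Small points are pool medians; squares are means over pools with SD.

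In the Cebpa knockout, no neutrophil-like or monocyte-like cell was seen. Of 847 knockout cells, 0 were neutrophil-like (which allows up to 0.354%, 3 counts of the total) against 13.4% of 558 control cells (interval 10.7 to 16.6), and 0 were monocyte-like against 9.86%. Dendritic-like cells made up 0.236% against 2.1505%. Erythroid-like cells were also a smaller share, 26.6% (interval 23.6 to 29.7) against 36.9% (32.9 to 41.1). Megakaryocyte-like cells made up 19.1% (16.5 to 21.9) against 6.09% (4.26 to 8.41), and 14.8% against 5.20% when marker genes were left out of the assignment. Cells of the unnamed clusters made up 39.9% against 17.7%. Stem- or multipotent-like cells (8.15% against 9.50%) and basophil- or mast-like cells (4.96% against 4.12%) differed less. Lymphoid- or NK-like cells were 1.06% against 0.179%. By exact two-sided permutation over pools, the neutrophil-like difference had p = 0.00404, the smallest value 495 splits allow (adjusted p = 0.00909), the erythroid-like difference p = 0.0202 (adjusted 0.0303) and the stem-like difference p = 0.230. The permutation treats pools as exchangeable, although they came in pairs from 4 knockout plates and 2 control plates, whose 15 splits are too few for a p under 0.05. Knockout pools kept 55.7% of their cells at 500 UMIs and control pools 73.4%, so shares are of the cells that passed.

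**Figure D3:**
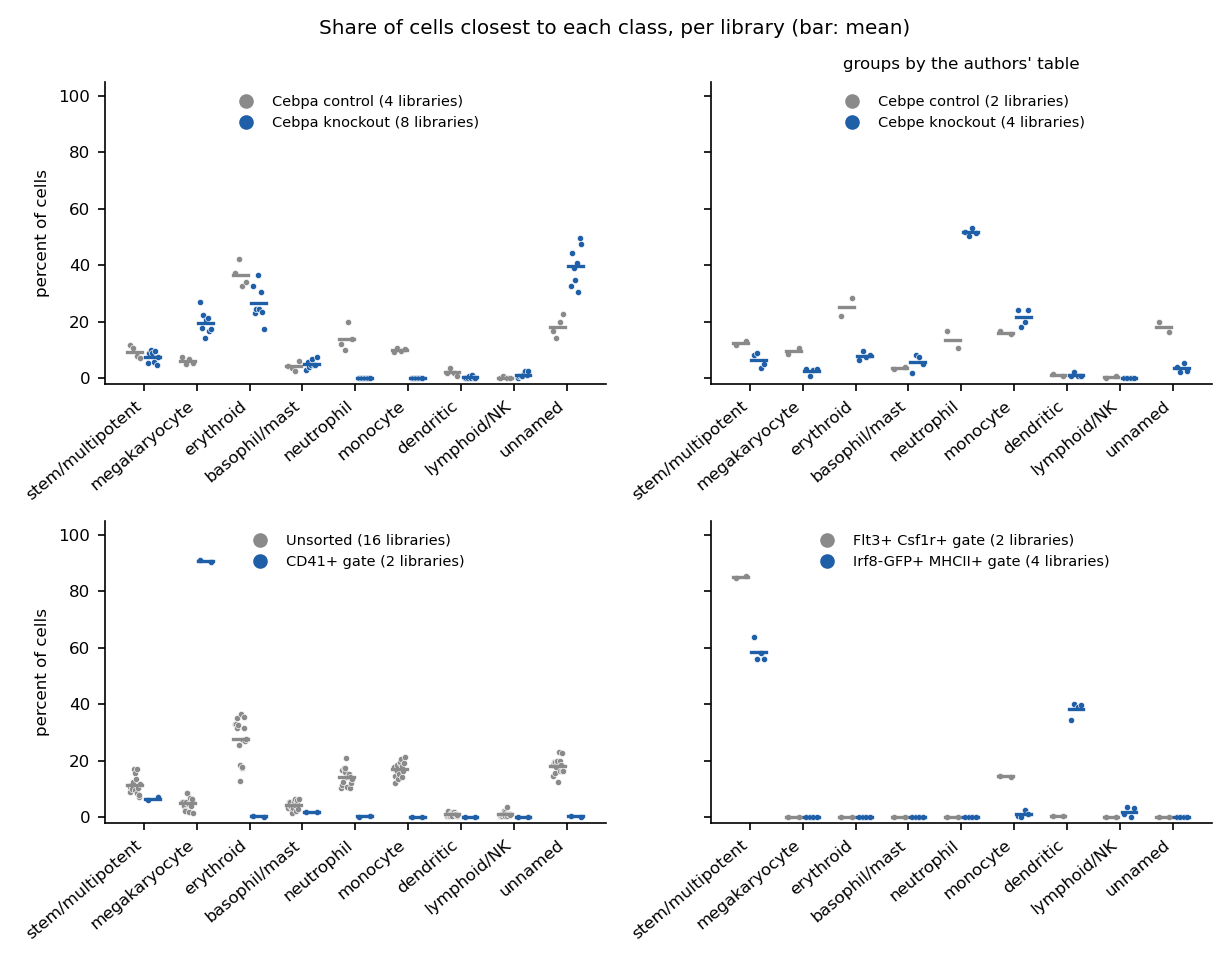
Share of cells in each class, as percent of the cells kept, for both knockouts with their controls and for the sorted gates. Points are amplification pools and bars are means.

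In the Cebpa knockout, genes of granulocytes and monocytes were lower and most erythroid genes stayed near the control level. By size, 26 genes were higher and 61 lower by 2-fold or more, of 2391 with at least 100 CPM. Cebpa itself was at 1.10 CPM against 101 (log2 ratio -6.51, interval -8.80 to -4.94; TMM-scaled pool ranges 0 to 4.2042 and 76.6 to 177). All 7 tested neutrophil genes and 5 of 7 primary granule genes fell (edgeR; 6 of 7 when adjusted over the list alone). List medians, here and below, are over all measured members with a ratio, tested or not: -5.52 for 13 neutrophil genes and -2.92 for 8 primary granule genes. Elane, the neutrophil elastase gene, stood at 40.9 CPM against 3038 (log2 -6.22, interval -6.50 to -5.95), Ctsg at 31.7 against 1907.5 (-5.91), Prtn3 at 118 against 4069.5 (-5.11) and Mpo at 246 against 4951 (-4.33). The protease inhibitor gene Slpi (-6.11), the haptoglobin gene Hp (-5.80), Emb (-4.52) and Gpc1 (-4.26) were lower by similar factors. Cebpe, also a granulocyte transcription factor gene, was lower at -5.52 (4 against 131 UMIs) and too sparse for the pool test. Of monocyte and dendritic genes, Irf8 was at 8.10 CPM against 132 (log2 -4.03, interval -4.73 to -3.40), Ly6c2 at -6.32, Cd74 at -2.55, the FcgR gene Fcgr3 at -2.38 and Csf1r at -1.925. The progenitor surface gene Cd34 was at -1.635. The heme synthesis gene Alas1 was at -2.61. Both tested secondary granule genes, both tested monocyte genes, 5 of 5 MHC class II genes and 4 of 5 dendritic genes fell in the edgeR pool test, with the same counts when adjusted over the list alone where not stated otherwise. The medians of these lists were -4.17 (6 measured), -4.03 (7), -1.36 (8) and -1.40 (7). With DESeq2, 3 MHC class II, 2 dendritic and 1 monocyte gene fell.

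Interferon-stimulated genes were the largest group higher without Cebpa: 6 of 8 tested rose and 0 fell (edgeR; also 6 when adjusted over the list alone), with a median log2 ratio of 1.29. Rtp4 (2.88), Xaf1 (2.28) and Ifitm3 (1.35) were among them. Ifitm1, of the basophil list, was at 665 CPM against 68.7 (3.28). Scin, which encodes an actin-severing protein, was at 137 CPM against 4.13 (5.05), and the granzyme gene Gzmb at 121 against 2 UMIs (5.43, interval 3.55 to 8.49). The thrombin receptor gene F2r (2.29), Spns2 (1.52), Txnip (1.502), Sox4 (1.455) and Kit (0.64, a joined row and uncertain, edgeR adjusted p = 0.0225) were also higher. Platelet genes had a median of 0.73, with 1 of 5 tested risen (3 of 5 when adjusted over the list alone). Erythroid genes had a median of 0.01 with 0 risen and 3 of 20 fallen (2 and 3 over the list alone). Of lineage transcription factors 1 rose and 3 fell of 15 tested, of heme synthesis genes 0 rose and 1 fell of 10 (1 and 1 over the list alone), of basophil genes 1 rose and 2 fell of 4, of stem genes 1 and 1 of 3, of lymphoid genes 2 and 0 of 5, and of immediate early genes 0 and 1 of 4. No S phase gene of 22 passed edgeR (unadjusted 9, DESeq2 0), and no globin or membrane gene of 10 did (unadjusted 1, DESeq2 0). Of 3 tested genes of other bone marrow cells 0 passed edgeR (unadjusted 0, DESeq2 0), and no eosinophil gene was measured. With DESeq2, 2 platelet genes, 1 erythroid gene, 1 heme synthesis gene and 0 lineage transcription factors rose. Over all genes, 167 rose and 296 fell of 5312 tested (edgeR, adjusted p under 0.05; 1427 at an unadjusted p under 0.05). Among 100 of the 495 ways to split the 12 pools, the real split gave 463 and the highest other gave 25. Leaving out 1 pool gave 71 to 136 genes by size and 221 to 940 by the test: 301 without knockout replicate 12, 889, 940, 221 and 259 without control replicates 3 to 6, and 136 by size without control replicate 4. Control replicates 5 and 6 shared a plate that stood apart from that of replicates 3 and 4; without replicates 5 and 6, 12 genes were higher and 45 lower by size, and without replicates 3 and 4, whose strain label names Mx1-Cre, 312 were higher and 383 lower (2628 by the test).

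Erythroid-like cells remained in both genotypes and were compared alone. By size, 7 genes were higher and 13 lower of 2327. Cebpa had 0 against 43 UMIs there (log2 -4.14 or lower), and Ctsg (-3.88), Mpo (-3.50), Prtn3 (-2.78) and Elane (-2.46) were lower. By edgeR 3 of 5 primary granule genes and 3 of 4 neutrophil genes fell (4 and 4 when adjusted over the list alone, 2 and 2 with DESeq2). The metallothionein gene Mt2 was at -1.01. Ifitm1 (3.21), Rtp4 (2.73), Xaf1 (1.87), Ifitm3 (1.35) and the blood group gene Kel (1.28) were higher. The interferon-stimulated list had a median of 1.35 with 10 of 11 measured members higher, but 0 of 5 passed edgeR over all genes (unadjusted 4, DESeq2 3; 4 when adjusted over the list alone). Car1 was at 0.58, and 0 of 20 erythroid genes rose while 1 fell (1 and 3 over the list alone). No heme synthesis gene of 9 (unadjusted 1, DESeq2 0), no globin or membrane gene of 11 (unadjusted 1, DESeq2 0) and no S phase gene of 23 (unadjusted 4, DESeq2 0) passed edgeR. Over all genes 1 (Ifitm1) rose and 6 fell of 4117 tested by edgeR (unadjusted 588; DESeq2 7 risen and 6 fallen). The real split gave 7 and the highest of the other splits tried gave 2, of 210 possible. Leaving out 1 pool gave 11 to 44 genes by size (42, 44, 11 and 12 without control replicates 3 to 6) and 2 to 7 by the test (4, 3, 3, 4, 3 and 2 without knockout replicates 5, 6, 7, 8, 11 and 12). Without control replicates 3 and 4 together 345 were higher and 340 lower by size. A check on background was added after these values were seen. Background at the level of the control wells without a cell, with the make-up of the pool, would give 34.2 of the 179 Elane UMIs in control erythroid-like cells (19.1%). It would give 12.7% of the Prtn3, 11.3% of the Ctsg and 6.6% of the Mpo UMIs. Those wells themselves held 444 UMIs, with 7 of Prtn3, 3 of Mpo and 0 of Elane and Ctsg. Their make-up may thus differ from that of the pool, and the background share of Prtn3 could be larger.

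**Figure D4:**
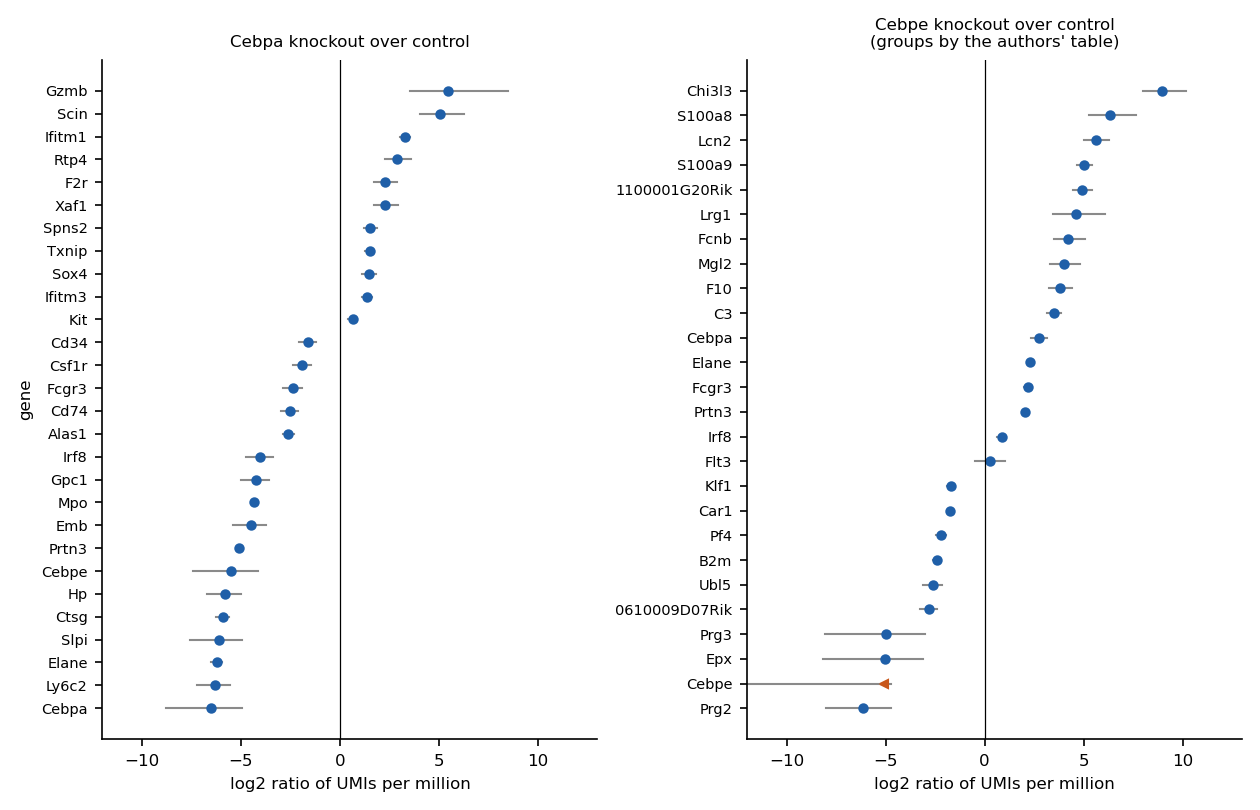
Log2 ratios of named genes with 95% intervals covering counting error only, for the Cebpa knockout and, by the authors' table, the Cebpe knockout against their controls. Orange arrows mark bounds set by the 3-count floor.

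By the authors' table, the Cebpe knockout was dominated by neutrophil-like cells. They made up 51.5% of 559 cells (interval 47.3 to 55.7) against 13.6% of 250 control cells (9.61 to 18.5), and 50.3% against 12.8% when marker genes were left out. Monocyte-like cells were 21.5% against 16.0%. Erythroid-like cells (7.87% against 25.2%), megakaryocyte-like cells (2.50% against 9.6%) and unnamed cells (3.40% against 18.0%) were lower. Stem- or multipotent-like cells were 6.62% against 12.4%, basophil- or mast-like 5.55% against 3.60%, and dendritic-like 1.07% against 1.20%. With 4 and 2 pools the exact permutation p could not go below 0.133 (adjusted 0.2), so no share could pass. The GEO labels give these pools other names and reverse the difference.

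Cebpe was not detected in the Cebpe knockout of the authors' table, at 0 against 61 UMIs (log2 -5.07 or lower), while Cebpa was higher, at 310 CPM against 46.2 (2.75). By size, 268 genes were higher and 101 lower of 2630. Genes of the secondary granule list, several of which Cebpe is known to activate, were higher. By edgeR 8 of 8 tested rose (8 when adjusted over the list alone), with a median of 4.24. Of the 14 members of the list 9 were measured, so the list as a whole was not read. Chi3l3 was at 3245 CPM against 6.49 (8.97), S100a8 at 458 against 5.68 (6.335), Lcn2 at 878 against 17.8 (5.62), S100a9 at 1624 against 49.5 (5.04) and Fcnb at 4.24. 1100001G20Rik (4.92), Lrg1 (4.61), the lectin gene Mgl2 (4.01), the coagulation factor gene F10 (3.81) and the complement gene C3 (3.52) followed. Primary granule genes rose in 8 of 9 (9 over the list alone; median 1.66), with Elane at 14536 CPM against 2966 (2.29) and Prtn3 at 2.02. Fcgr3 (2.19) and Irf8 (0.86) were higher and Flt3 was near its control level (0.25). Of neutrophil genes 13 rose and 1 fell of 14 tested, of monocyte genes 5 rose and 0 fell of 8 (6 over the list alone), and of basophil genes 4 rose and 0 fell of 6 (5 and 1 over the list alone; 2 rose with DESeq2).

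Erythroid genes fell in 19 of 21 (21 when adjusted over the list alone; median -1.53), globin and membrane genes in 9 of 11 (10; median -1.33) and heme synthesis genes in 7 of 12 with 1 risen (8 and 1; median -0.85). Car1 (-1.72), Klf1 (-1.70), the platelet factor gene Pf4 (-2.20), B2m (-2.42, a joined row and uncertain), Ubl5 (-2.63) and 0610009D07Rik (-2.83) were lower. Of platelet genes 1 rose and 6 fell of 11 (2 and 6 over the list alone), of lineage transcription factors 6 rose and 9 fell of 21 (7 and 11), of interferon-stimulated genes 0 rose and 4 fell of 11 (0 and 4), of S phase genes 0 rose and 3 fell of 23 (0 and 2), and of immediate early genes 2 rose and 1 fell of 8. Of MHC class II genes 1 of 5 rose, of stem genes 2 of 5 fell, of lymphoid genes 1 rose and 1 fell of 4, of dendritic genes 2 of 6 rose (2 and 1 fallen over the list alone), and the 1 tested gene of other bone marrow cells rose. With DESeq2, 5 globin or membrane, 3 platelet, 1 S phase and 1 stem gene fell, and 1 immediate early, 0 platelet and 0 MHC class II genes rose. The eosinophil genes Prg2 (-6.13), Epx (-5.04) and Prg3 (-4.97, a joined row and uncertain) were lower, but 1 of the 2 control pools held all of Prg2 (0 to 272 CPM) and they could not be tested. Over all genes 995 rose and 726 fell of 7369 tested by edgeR. Leaving out 1 pool gave 354 to 439 genes by size and 908 to 1652 by the test, 908 without the control pool labelled Cebpa knockout replicate 4. These values cover all cells, and the class shares of the groups differed as given above.

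Within neutrophil- and monocyte-like cells, secondary granule genes were also higher in the Cebpe knockout of the authors' table. The mix of the 2 classes differed: 288 neutrophil-like and 120 monocyte-like cells in the knockout, 34 and 40 in the control. By size 89 genes were higher and 53 lower of 2482. Of secondary granule genes 7 of 8 rose (edgeR; 7 when adjusted over the list alone; median 3.26), with Chi3l3 at 8.25, S100a8 at 7.145 (741 against 1 UMI), Lrg1 at 5.49 (235 against 1 UMI), Lcn2 at 4.45 and S100a9 at 3.56. Dgat2, an enzyme gene of triglyceride synthesis, was at 3.66 (198 against 3 UMIs). Cebpa (1.51) and Elane (0.81) were higher and Cebpe was -6.56 or lower. Primary granule genes rose in 3 of 8 (5 over the list alone; median 0.49), and of neutrophil genes 9 rose and 1 fell of 14 (10 and 1; median 0.78). B2m (-2.44, a joined row and uncertain), Ubl5 (-2.07), Pf4 (-3.05) and Klf1 (-2.08) were lower. Erythroid genes fell in 5 of 10 (9 over the list alone, median -1.54). Background from other cells was not estimated for these pools, in which erythroid-like cells were 7.87% of knockout and 25.2% of control cells. Prg2 (-8.73), Prg3 (-6.43) and Epx (-5.89 or lower) were lower, again from 1 control pool. Of lineage transcription factors 2 rose and 4 fell of 15 (3 and 6 over the list alone), of platelet genes 0 rose and 2 fell of 4 (1 and 2), and of basophil genes 0 rose and 2 fell of 4 (2 and 2). With DESeq2, 1 transcription factor rose and 1 fell, and 0 platelet and 0 neutrophil genes fell. No monocyte gene of 7 (unadjusted 2, DESeq2 0, 1 fallen when adjusted over the list alone) and no S phase gene of 21 (unadjusted 4, DESeq2 0) passed edgeR. Over all genes 135 rose and 69 fell of 5710 tested by edgeR. Leaving out 1 pool gave 146 to 274 genes by size and 61 to 169 by the test: 274 and 61 without the control pool labelled Cebpa knockout replicate 3, and 81 by the test without the one labelled replicate 4.

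At the main clustering resolution the CD41-positive gate was almost all megakaryocyte-like. Such cells made up 90.8% of 336 (interval 87.2 to 93.6) against 4.94% of unsorted cells, and stem- or multipotent-like cells 6.55% against 11.5%, with an exact permutation p of 0.0131 for the megakaryocyte share, the smallest of 153 splits (adjusted 0.0147). The gate sets this share by design. Its difference from unsorted cells was 85.8 points at the main resolution and 56.8 at the lower resolution. At the lower resolution the megakaryocyte-like cluster was wider and held 23.4% of unsorted cells before assignment. By size 351 genes were higher and 386 lower of 2748. All 14 tested platelet genes rose (edgeR; 14 when adjusted over the list alone; median 4.79): Pf4 at 7.64, Treml1 at 7.00, Vwf at 5.64 and, from joined rows that stay uncertain, Gp1bb at 6.54 and the CD41 gene Itga2b at 6.06. Pde10a (6.74), the endothelial adhesion gene Esam (6.49) and the thromboxane receptor gene Tbxa2r (6.16) were as high. The transcription factor genes Meis1 (4.14) and Gata2 (2.43) were higher. Erythroid genes fell in 20 of 21 with 1 risen (median -3.13), neutrophil genes in 11 of 11 (-3.08), globin genes in 10 of 11 (-2.74), heme synthesis genes in 11 of 12 (12 over the list alone) and monocyte genes in 7 of 11 (8). Ermap (-5.92), Rhag (-5.44), Car1 (-4.93), Klf1 (-3.89), Elane (-5.70), Prtn3 (-3.10), Ctsg (-3.065), Mpo (-2.935), Fcgr3 (-4.49), Irf8 (-3.26), Cebpa (-2.19), Csf1r (-1.98), Kit (-1.11) and Cd34 (-0.76) were lower. Cldn13 was at -7.21 from 1 UMI. Over all genes 1738 rose and 1902 fell of 8533 tested. Within the sequencing batch both groups share, 354 were higher and 385 lower by size. The test count fell to 2294 and 2095 of 3640 when CD41 replicates 1 and 2 were left out in turn (range 2095 to 3688).

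The Flt3- and Csf1r-positive gate held stem- or multipotent-like cells (85.0% of 380, interval 81.0 to 88.4, against 11.5%) and monocyte-like cells (14.5% against 17.0%). Of the other cells 2 were dendritic-like, and no cell of another class was seen, which allows up to 0.789% each (3 counts of the total). The gate was sorted on Flt3, 1 of the 3 markers (with Cd34 and Sox4) that named the stem- or multipotent-like cluster. The gate thus sets this share by design, and the name does not show multipotency. Without marker genes in the assignment, monocyte-like cells were 21.8% against 17.6%, and after thinning 17.6% against 16.4%, so the direction of that difference was not stable. By size 315 genes were higher and 311 lower of 2744. Both sorted receptors were higher at the mRNA level, Flt3 at 4.01 and Csf1r at 2.445. Satb1 (3.50), Gpr171 (3.31), Lat2 (3.13), Lsp1 (3.015), Serpinf1 (3.14), Dntt (2.70), Cd34 (2.82), Sox4 (2.21), Irf8 (2.57), H2-DMa (2.46) and Cst3 (1.54) were higher, as was AK156292 (3.18), from a joined immunoglobulin row that stays uncertain. Cebpa (0.88) and Mpo (0.76) were higher, Kit was near the unsorted level (-0.31), and Elane (-1.905), Fcgr3 (-3.37) and Cebpe (-3.70) were lower. Erythroid genes fell in 21 of 21 (edgeR; 21 over the list alone; median -5.98) and globin and membrane genes in 11 of 11 (-5.35): Car1 was -10.19 or lower, Mt2 -9.67, Aqp1 -7.93, Klf1 -7.905, Ermap -7.61 or lower, Gata1 -6.505 or lower and Gfi1b -4.77. The platelet gene Gp5 was at -4.44 from 1 UMI. Monocyte genes rose in 5 of 11 and fell in 1 (median 1.05), stem genes rose in 4 of 7 and fell in 1 (0.71), MHC class II genes rose in 4 of 8 and fell in 2 (0.93), heme synthesis genes fell in 10 of 12 (-1.63) and platelet genes in 7 of 13 with 1 risen (-1.59). Over all genes 1696 rose and 1707 fell by edgeR, and without Flt3 replicates 1 and 2 in turn 2172 and 1792 passed (range 1792 to 3465). The gate was sequenced in another batch than the unsorted pools, so batch and gate cannot be told apart.

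The Irf8-GFP- and MHC class II-positive gate added dendritic-like cells, 38.4% of 743 (interval 34.8 to 42.0) against 1.10%, to stem- or multipotent-like cells at 58.5% against 11.5%. Lymphoid- or NK-like cells were 2.02% and monocyte-like cells 1.08%. The exact permutation p for dendritic-like cells was 0.000413, the smallest of 4845 splits (adjusted 0.000464). The gate was sorted on MHC class II, and MHC class II genes were among the markers that named the dendritic-like cluster. The gate thus sets this share by design and favours the rise of those genes. Pools came in pairs from the same plate, which the permutation does not model. By size 246 genes were higher and 275 lower of 2778. MHC class II genes rose in 9 of 9 (edgeR; 9 over the list alone; median 5.39) and dendritic genes in 10 of 11 (5.77): H2-Eb1 at 7.40, H2-Aa at 6.94, Cd74 at 6.24, H2-Ab1 at 6.06, the chemokine receptor gene Xcr1 at 9.185, Batf3 at 5.77, Id2 at 5.03, Plbd1 at 5.80 and Ckb at 5.63. The chemokine gene Ccl22 was at least 8.415. Monocyte genes rose in 9 of 11 with 1 fallen (1.75), with Lgals3 at 4.49 and Mpeg1 at 3.91, and stem genes in 6 of 7 with 1 fallen (1.65). Flt3 (4.23), Cd7 (4.48), Cd34 (2.19), Irf8 (1.79), Csf1r (0.81) and Kit (0.51) were higher. Col1a1 (8.66) and C1qa (6.54), of the list of other bone marrow cells (5 of 5 risen; median 3.51), were high too. Car1 (-11.93), Sphk1 (-9.94), Klf1 (-8.06), Gata1 (-7.66), Ermap (-8.76 or lower) and Aqp1 (-8.50 or lower) were lower with 21 of 21 erythroid genes fallen (-5.73), as were Elane (-3.37), Hp (-2.67) and Fcgr3 (-2.24) with 10 of 11 neutrophil genes fallen (11 over the list alone). Over all genes 2176 rose and 2059 fell by edgeR. The real split gave 4235 and the highest of the other splits tried, which kept 3 of the 4 gate pools together, gave 2742, so chance is excluded only down to that split. Gate and sequencing batch were again the same split of the pools.

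**Figure D5:**
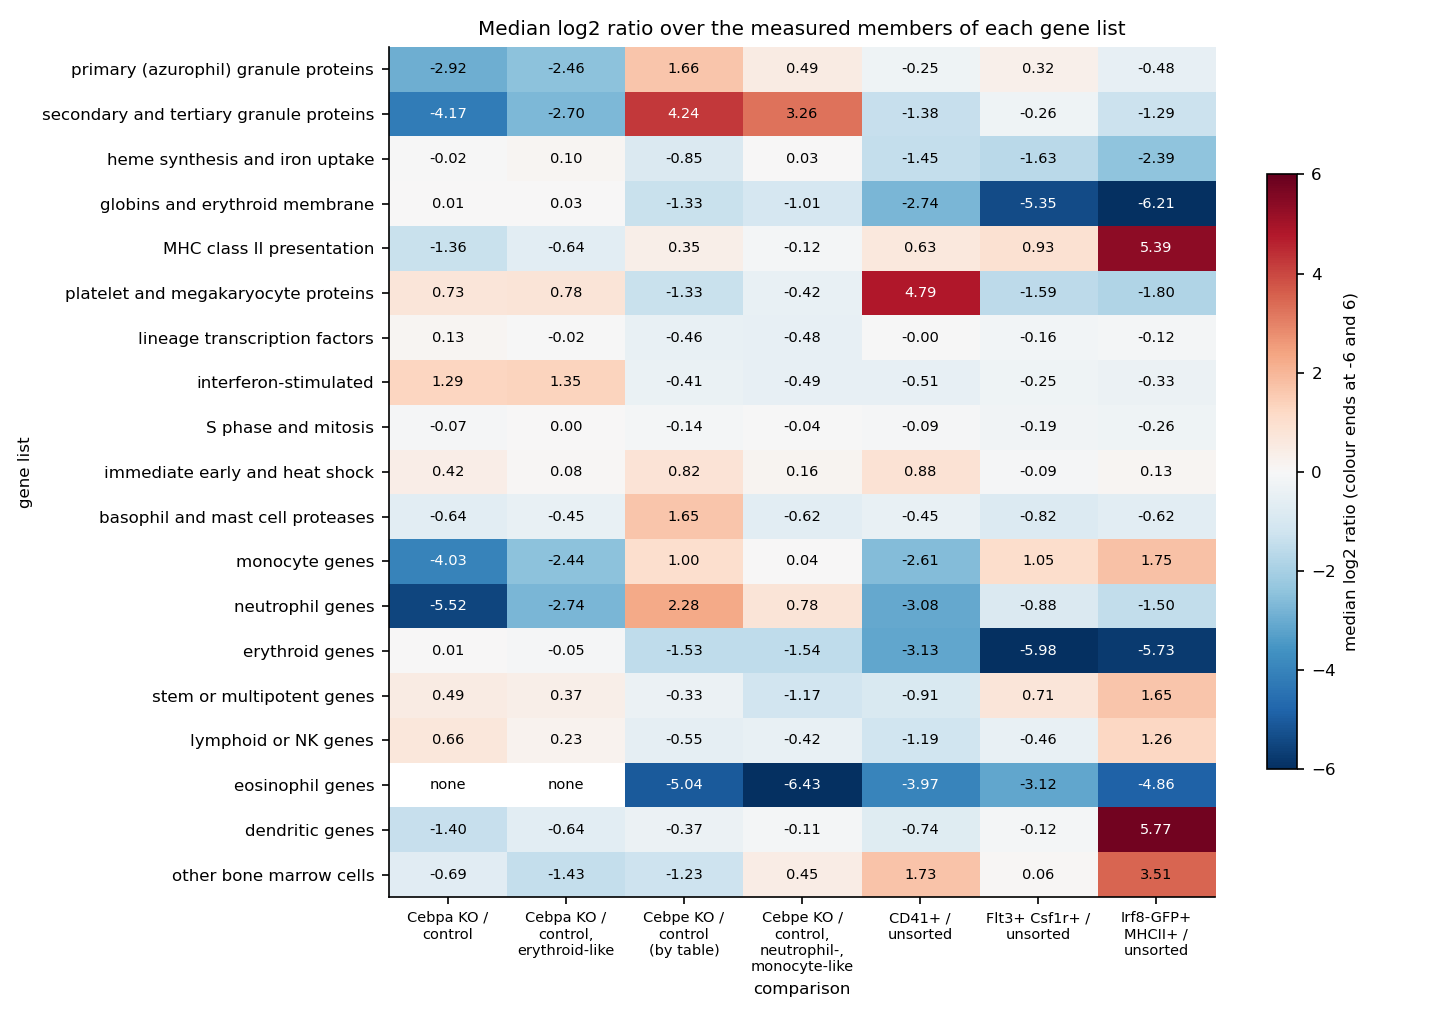
Median log2 ratio of each fixed gene list in the knockouts, by the authors' table for Cebpe, and in the sorted gates against unsorted cells. Colours end at 6 in each direction.

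The remaining fixed lists of the gates against unsorted cells split as follows by edgeR. In the CD41 gate primary granule genes rose in 2 and fell in 4 of 9, secondary granule genes fell in 3 of 5 (4 over the list alone), MHC class II genes rose in 2 and fell in 1 of 8, lineage transcription factors rose in 9 and fell in 10 of 22, interferon-stimulated genes rose in 1 and fell in 3 of 13, and S phase genes rose in 5 and fell in 7 of 23 (6 and 7). Immediate early genes rose in 5 and fell in 1 of 10, basophil genes 1 and 1 of 6, stem genes 2 and 4 of 7, lymphoid genes 1 and 1 of 7, dendritic genes 0 and 2 of 9 and other marrow genes 2 and 0 of 3. In the Flt3 gate primary granule genes rose in 3 and fell in 3 of 9, secondary granule genes fell in 2 of 5 (1 risen and 2 fallen over the list alone), transcription factors rose in 9 and fell in 8 of 22 (9 and 9), interferon-stimulated genes 3 and 4 of 13, S phase genes 2 and 7 of 23 (2 and 8) and immediate early genes 2 and 2 of 10. Basophil genes rose in 2 and fell in 2 of 6, neutrophil genes 2 and 6 of 11 (2 and 7), lymphoid genes 2 and 1 of 7 (median -0.46), dendritic genes 2 and 3 of 9 (-0.12) and other marrow genes 1 and 0 of 3. In the Irf8-GFP gate primary granule genes rose in 2 and fell in 4 of 9, secondary granule genes fell in 3 of 5, heme synthesis genes in 11 of 12 and globin genes in 11 of 11. Platelet genes rose in 3 and fell in 8 of 13, transcription factors 10 and 9 of 22, interferon-stimulated genes 2 and 4 of 13 (2 and 3), S phase genes 4 and 6 of 23, immediate early genes 5 and 3 of 10, basophil genes 2 and 3 of 6 (3 and 3) and lymphoid genes 6 and 0 of 7 (6 and 1). Eosinophil genes fell in 2 of 3 in the Irf8-GFP gate (3 over the list alone) and passed edgeR in 0 of 3 in the CD41 gate (unadjusted 0, DESeq2 1) and 0 of 3 in the Flt3 gate (unadjusted 1, DESeq2 2).

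The gates also differed from each other. Flt3-gate cells against CD41-gate cells had 256 genes higher and 245 lower by size of 2623: Ly86 (6.76), Irf8 (5.83), Flt3 (5.08), Csf1r (4.43) and Cd34 (3.58) were higher and Pf4 (-9.23), Vwf (-8.56) and Itga2b (-8.06, joined row) lower. Platelet genes fell in 12 of 14 (edgeR; 13 over the list alone), neutrophil genes rose in 7 of 7 and monocyte genes in 8 of 10 (9). Irf8-gate cells against CD41-gate cells had 423 higher and 453 lower of 2755, with H2-Aa (9.27), Cd74 (8.87), Id2 (7.07) and Cd34 (2.99) higher, Pf4 (-11.62), Gp5 (-10.12) and Itga2b (-7.22) lower, and 9 of 9 MHC class II genes risen. Irf8-gate cells against Flt3-gate cells had 201 higher and 109 lower of 2622: H2-Eb1 was at least 9.86, H2-Aa 8.36, Cd74 8.09, Plbd1 7.54 and Id2 6.28, while Cd34 (-0.60), Irf8 (-0.75), Csf1r (-1.60) and Hp (-2.46) were lower and Flt3 was near equal (0.26). Prdx1 was at -4.97, but at 0.081 between pools of 1 sequencing batch by the authors' table. Dendritic genes rose in 10 of 11 and fell in 1, and neutrophil genes fell in 6 of 9. By edgeR over all genes, 791 rose and 742 fell, 1968 rose and 1777 fell, and 912 rose and 877 fell in these 3 comparisons. Across genes, which are not independent replicates, the Irf8-to-Flt3 ratio had a Spearman rho of -0.424 with the GC content of transcript 3' ends, and the 2 gates shared no batch. Leaving out 1 pool gave 877 to 996 genes by the test for Flt3 against CD41 (877, 899, 974 and 996 without CD41 replicates 1 and 2 and Flt3 replicates 1 and 2). It gave 2327 to 3892 for Irf8 against CD41 (2455 and 2327 without CD41 replicates 1 and 2) and 534 to 2052 for Irf8 against Flt3 (926, 534 and 1184 without Flt3 replicates 1 and 2 and Irf8 replicate 3).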

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

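Of the 3 patterns weighed here, the tests on the labels, on interferon within erythroid-like cells and on other splits of the pools were chosen after the result was seen; the others had their outcomes written down before they were run. None of the tests was planned before the data were examined.

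The GEO labels and the authors' table differed for 18 pools. Moving the labels of samples 21 to 42 by 2 places matched 22 of 22 entries of the table, against 4 with no move and at most 13 with any other move, which fits a shift of labels in the deposit. An error in the table was weighed too: of 8 pools whose group could be decided from other pools, 0 had a profile closer to the label's group. Their correlation across genes, which are not independent replicates, was 0.912 to 0.970 with the group of the table and 0.7102 to 0.902 with that of the label. The GEO record itself was not checked against tubes or sort sheets, so the source of the shift stays open.

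The 2 Cebpa control pools of plate 27 (replicates 5 and 6) stood apart from the 2 of plate 26 (replicates 3 and 4), with 75 genes 2-fold higher and 423 lower, such as Rpl23 (174 CPM against 1475), Eef1a1 (139 against 2400.5), Hsp90aa1 (56.7 against 876) and Rpl18 (3236 against 1319). Thinning the summed UMIs of plate 26 to those of plate 27 put 0 genes 2-fold apart from plate 26 at full depth. Random loss of UMIs from the sum thus did not give the pattern. The draw could hardly move genes of 100 CPM or more by 2-fold. It models neither depth per cell nor amplification, so other effects of depth stay open. Shares of cell classes were excluded, since the median difference within erythroid-like cells was 1.077 times that in all cells. GC content of transcript 3' ends fits (Spearman rho 0.346 across genes, which are not independent replicates), and transcript length could not be decided (-0.272). The ratio also followed that between unsorted plates 4, 6 and 8 and plates 5, 7 and 9 (rho 0.4501), which fits a difference in library preparation shared by those plates. The ratio between the unsorted plates itself had a rho of 0.31 with GC content, so these 2 relations are not independent of each other. The strain label names Mx1-Cre for the pools of plate 26 only, so strain and plate could not be told apart, and no biological explanation was tested.

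Interferon-stimulated genes were higher in the Cebpa knockout, with a median log2 ratio of 1.29 over 8 tested genes. Shares of cell classes were excluded (1.22 within erythroid-like cells, 8 of 8 higher), as were the control pools of plate 27 (1.16 without them) and a difference limited to the later sequencing batch (1.65 in the earlier batch, by the authors' table). Both groups carry the poly(I:C) label, an inducer of interferon, but the labels of these pools give no dose or time (some earlier pools have them, under labels that differ from the table). With 1 mouse identifier per genotype, a difference between animals in that response cannot be separated from the genotype, and it was not tested.

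Chance as an explanation was tested by splitting the pools at random. For the Cebpa knockout the real split gave 463 genes and the highest other 25, and within erythroid-like cells 7 and 2, which excludes chance only if pools are exchangeable. Pools came in pairs from plates, 4 of the knockout and 2 of the control, plates 26 and 27 differed in many genes, and the 15 splits by plate are too few for a share under 0.05, so chance between plates stays open. For the Irf8-GFP gate the real split gave 4235 and the highest other 2742, from a split that kept 3 of the 4 gate pools together, and among 100 splits only the real one reached its count.

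Single pools far from the others of their group were listed for 30 of 207 groups of values. Chance would give about 1 in 20 if values were normally distributed, but a group in which all pools but 1 held 0 is always listed. The CPM of listed pools are given without TMM scaling. Cebpa knockout replicate 5 held the highest CPM of Elane (182; others 0 to 20.8), Ctsg (131; 0 to 40.1), Prtn3 (372; 20.0 to 98.97), Mpo (527; 56.0 to 270) and Ly6c2 (24.8; 0 to 3.61), and the lowest of Rtp4 (40.5; 82.5 to 118). In its erythroid-like cells Ctsg (40.5; 0 to 12.5), Prtn3 (177; 0 to 23.7) and Elane (114; 0 to 13.3) were again the highest. In other knockout pools Slpi was high in replicate 6 (10.4; 0 to 4.50), Cd74 in replicate 7 (104.6; 3.46 to 33.0), and Scin (313; 104 to 162), Ifitm1 (1212; 577 to 786) and Kit (305; 136 to 191) in replicate 9. F2r was low in replicate 10 (24.1; 64.0 to 96.9), and Ifitm3 was high in erythroid-like cells of replicate 8 (247; 123 to 160). Cebpa control replicate 4 was the only pool of its group with a lymphoid- or NK-like cell (1 cell, 0.617%).

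In the Cebpe knockout of the authors' table, the pool labelled Cebpa control replicate 1 was the highest in S100a8 (806; others 299 to 379), Lcn2 (940.4; 787 to 812) and Epx (4.54; 0). The pool labelled Cebpa control replicate 2 was the highest in Car1 (1509.9; 776 to 878), in Prg3 (4.62; 0, and 6.68 in neutrophil- and monocyte-like cells) and in the dendritic-like share (2.07%; 0.637 to 0.826), and the lowest in the megakaryocyte-like share (0.690%; 2.94 to 3.31). Pf4 was the highest in the pool labelled Cebpe control replicate 1 (234; 23.1 to 47.7). In the Irf8-GFP gate, Batf3 was highest in replicate 5 (168; 95.5 to 104), Car1 in replicate 6 (3.86; 0) and Sphk1 and Gp5 in replicate 4 (1.59 each; 0). The wells without a cell, used only for the check on background, held signal: a median over pools of 58.75 UMIs per well (12.5 to 212).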

How the results depend on the processing

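Some of these alternatives were chosen after the data were seen: grouping by label or by table, the earlier batch, the batch covariate by table, leaving out plate 27, and leaving out knockout pools under 50 cells. Of 3877 recomputed values of 190 gene and comparison pairs, 3296 stayed the same, 551 moved and 30 reversed. The same means a change smaller than the standard error over pools, or than the counting interval where there was none. Reversed means a change of sign in a gene 2-fold or more apart with at least 100 CPM in the higher group. Sign changes of smaller differences are counted among the other values. Counts by size stayed within 1.5 times in 174 of 197 settings, and counts of the pool test in 130 of 189. Shares and surface intensities were called the same if they changed by less than the SD over pools, combined over both groups for shares. This held for 126 of 136 shares and 306 of 306 intensities. Most settings for intensities left out 1 of 16 pools. That can hardly move a mean by its SD, so the last count was nearly fixed in advance. Causes of the moves below were not tested except where fewer UMIs or fewer pools make the setting itself. No paired analysis was possible because no label or table entry pairs pools across groups. A batch covariate among the 12 Cebpa pools, an animal block and a replicate block could not be run, since all those pools share 1 batch, each group has 1 mouse identifier, and replicate numbers do not pair pools. At resolution 0.5 no stem- or multipotent-like class was left for the Flt3 gate. With knockout pools under 50 cells left out, the pools compared within erythroid-like cells were unchanged.

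For the Cebpa knockout (87 by size, 463 by test), thinning to 500 UMIs gave 287 (141 higher, 146 lower) and 127 (68, 59), dropping controls whose strain label names Mx1-Cre gave 695 (312, 383) and 2628 (1356, 1272), dropping plate 27 gave 57 (12, 45) and 296 (133, 163), and the earlier batch by table gave 236 (166, 70) and 739 (488, 251). The pool as unit gave 182 by size (95, 87). By test, no filter gave 805 (268, 537), the GEO label 68 (21, 47), grouping by the authors' table gave 1086 (573, 513) with 53 higher and 60 lower by size, dropping pools under 50 cells 301 (91, 210) and the batch covariate with that grouping 1113 (578, 535). Within erythroid-like cells (20 and 7), thinning gave 366 (217, 149) and 1, dropping the Mx1-Cre controls 685 (345, 340) and 1745 (942, 803), dropping plate 27 9 (2, 7) and 37 (25, 12), the earlier batch 204 (181, 23) and 311 (273, 38), the label 40.0 (36, 4) and 3, grouping by table gave 52 (45, 7) and 193 (128, 65), and the pool as unit 116 (94, 22). By test, no filter gave 146 (78, 68), the batch covariate 198 (134, 64), 1000 UMIs 4, DESeq2 13 (7, 6), and assignment without markers split 2 higher and 5 lower.

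For the Cebpe knockout (369 and 1721), thinning gave 304 higher and 237 lower by size and 210 by test (135, 75), and the label 185 and 362 by size. Within neutrophil- and monocyte-like cells (142 and 204), thinning gave 638 (406, 232) and 31 (24, 7), the label 405 (133, 272) and 620 (215, 405), DESeq2 103 by test (70, 33) and no filter 113 higher and 42 lower by size. Thinning gave, by test, 980 (469, 511) for the CD41 gate, 769 (380, 389) for Flt3, 1137 (611, 526) for Irf8-GFP with 293 higher and 219 lower by size, 349 (185, 164) for Flt3 against CD41, 1037 (563, 474) for Irf8 against CD41 and 370 (223, 147) for Irf8 against Flt3, with 548 (358, 190) by size in the last. The label gave 287 by size for Flt3 (156, 131), 2243 by test for Irf8 against CD41 (1242, 1001), and 24 (1, 23) and 88 (3, 85) for Irf8 against Flt3, where grouping by table gave 3260 by test (1714, 1546). With the pool as unit the Irf8-GFP gate split 313 higher and 202 lower. With no filter the median of all genes shifted by -0.126 for CD41 (274 higher, 461 lower) and -0.111 for Flt3 (263, 405); DESeq2 shifted none by more than 0.048. With DESeq2, among gate lists, 2 MHC class II genes and 2 lymphoid genes fell in the CD41 gate and 0 platelet genes rose in the Flt3 gate. Within 1 batch by the table, Irf8 against Flt3 gave 171 higher and 65 lower.

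Leaving out 1 pool gave, by size and test, 71 to 136 and 221 to 940 for Cebpa, 11 to 44 and 2 to 7 in its erythroid-like cells, 354 to 439 and 908 to 1652 for Cebpe, 146 to 274 and 61 to 169 in its neutrophil- and monocyte-like cells, 719 to 810 and 2095 to 3688 for CD41, 603 to 748 and 1792 to 3465 for Flt3, 516 to 577 and 3559 to 4301 for Irf8-GFP, 519 to 556 and 877 to 996 for Flt3 against CD41, 779 to 979 and 2327 to 3892 for Irf8 against CD41, and 259 to 400 and 534 to 2052 for Irf8 against Flt3. A lone pool left in a gate is assumed to vary like the other groups.

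The neutrophil- or monocyte-like difference was -23.3 points for Cebpa (-24.5 to -21.8 without 1 pool; -33.4 by label) and the neutrophil-like one 37.9 for Cebpe (34.985 to 40.951; -46.3 by label, reversed). The megakaryocyte-like difference of the CD41 gate was 85.6 to 86.1 without 1 pool and 56.8 at resolution 0.5. The stem-like difference of the Flt3 gate was 73.3 to 73.9 without 1 pool, 69.8 thinned, 48.5 by label, 66.7 by table, 66.5 without markers and 68.0 at resolution 1.5. Before component scores were rounded, the last of these was far lower, so shares at resolution 1.5 are not stable. The dendritic-like difference of the Irf8-GFP gate was 36.7 to 38.5 without 1 pool, 24.4 by label and 34.551 at 1000 UMIs. The erythroid-like share of unsorted cells was 27.0 to 28.7 without 1 pool. Without 1 pool, CD34 ranged over 42.2 to 44.3 in erythroid-like, 226 to 237 in neutrophil-like, 314 to 329 in monocyte-like, 169 to 186 in megakaryocyte-like, 249 to 262 in stem-like, 381 to 421.5 in basophil-like, 139 to 155 in dendritic-like, 26.1 to 32.3 in lymphoid-like and 60.2 to 65.0 in unnamed cells. FcgR ranged over 10.1 to 11.1, 1449 to 1560.4, 1713 to 1812, 246 to 271, 336 to 365, 1418 to 1589, 194 to 223, 499 to 592 and 100 to 106.3 in the same order.

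Of the 30 reversed genes, 29 reversed when pools were grouped by the GEO label, where pools labelled Cebpe knockout are Cebpa pools in the authors' table and those labelled Cebpe control are its Cebpe knockout. These were Irf8 (0.16) for Cebpa, and for Cebpe Chi3l3 (-5.10), S100a8 (-5.02), Lcn2 (-5.91), S100a9 (-5.39), Lrg1 (-5.76), Fcnb (-3.40), Mgl2 (-3.53), F10 (-3.84), C3 (-3.70), 1100001G20Rik (-5.56), Cebpa (-2.43), Elane (-3.08), Prtn3 (-2.66), Fcgr3 (-4.17), Prg2 (4.62), Pf4 (0.0175), Car1 (2.48), Klf1 (2.01) and B2m (0.54). Within neutrophil- and monocyte-like cells they were Cebpe (6.36), Chi3l3 (-4.55), S100a8 (-3.96), Lrg1 (-4.79), Lcn2 (-4.03), S100a9 (-5.56), Dgat2 (-1.15), Cebpa (-0.93) and B2m (0.62). Prdx1 between the Irf8 and Flt3 gates turned to 0.081 within 1 batch. Of the gene list medians, lineage transcription factors in the CD41 gate, other bone marrow cells in the Flt3 gate and S phase genes in Cebpe neutrophil- and monocyte-like cells and in Cebpa erythroid-like cells lay near 0 and changed sign with the scaling. Depth limits what can be called: 500 UMIs per cell left fewer genes past every pool test.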

Other observations

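The counts of cells per cluster in this part were chosen after their values were seen, and no test was run on them.

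Cells of the unnamed clusters were the largest group in the Cebpa knockout, at 39.9% of cells against 17.7% in its control. The larger unnamed cluster was led by Apoe, Ptpn14 and Slc22a3, with Gata2 and F2r also among its leading genes. Over all cells of the knockout, F2r (log2 ratio 2.29), Scin (5.05) and Gzmb (5.43) were higher. These ratios were not read within the cluster. F2r is also on the platelet list and Gzmb on the lymphoid or NK list, and cells of both classes were a larger share in the knockout. Of erythroid-like cells, 90 and 135 fell into the 2 erythroid-like clusters in the knockout, against 51 and 155 in the control.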
